A study of Mus musculus with 18 samples.

How the data were processed

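Neutrophils were sorted from spleens of untreated female NZBWF1/J mice as live single cells positive for Ly6B, CD11b and Ly6G with intermediate Ly6C, per the labels' protocols, which also give the kits named here. Total RNA was isolated with the RNeasy Plus Micro kit, and libraries were made from 1 ng of cDNA with the Nextera XT kit and read from a single end, 100 nt per read. The labels list the molecule as polyA RNA. Titles place 6 mice in each of 3 age groups (14, 20 and 26 weeks), and every group and replicate number was taken from them. The labels give no sequencing date, run or lane per sample, so no batch could be entered in a fit.

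The values are raw read counts per gene symbol, which the authors made, per the submitters' processing notes, with Trimmomatic 0.32, STAR 2.4.2a, HTSeq 0.6.1, DESeq2 1.12.3 and DESeq on the GRCm38.p4 build. The notes do not say which step each tool did, and the gene annotation and the strand setting of the counting are not given in the sources used here. The deposited table holds 17941 symbols in 18 columns of whole numbers, 1 column per mouse, and its smallest gene total over the 18 libraries is 2. The values were checked for that unit: all are whole and library totals differ. A filter on low totals is not described in the notes. Symbols were placed on GRCm38 with GENCODE M21 gene models, 16809 directly and 454 through a RefSeq synonym, and 678 were not matched and carry no coordinates.

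Library totals ran from 5546624 to 17256379 counts. The counts are reads without molecular identifiers, and floors on counts cover counting error only. The SE and SD given with values also take in differences between mice. Replicates differed by more than counting error, with a mean chi-square per gene from 27.8 to 199 over pairs of libraries of the same age. A fold against an age with 0 counts was bounded with 3 counts over the 6 libraries of that age, and 19, 9 and 20 of the genes called in 20 against 14, 26 against 14 and 26 against 20 weeks had 0 counts in an age.

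Genes were tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr by age, robust quasi-likelihood fits and quasi-likelihood F tests, in 1 fit of all 18 libraries with age as the only term. There were 5 results: the 3 pairs of ages, 20 weeks against the mean of 14 and 26 weeks, and a test of any change with age. Benjamini-Hochberg adjusted p under 0.05 was the threshold, over the 10104 genes tested. The SE of a log2 fold change was taken as its size over the square root of F. Fitted fold changes rest on edgeR's own prior count. Log2 CPM used a prior count of 2.

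Gene lists (26 of neutrophil programmes and 11 of other cell types) and 37 single genes were fixed before the data were examined, together with the tests, the rule for naming genes and the alternatives not marked otherwise. Lists with at least 5 tested members were compared with other genes by camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the 28 lists tested, and also with an estimated correlation and with fry. The fry test asks whether the genes of a list move, on balance, in 1 direction, without comparing them with other genes. Calls adjusted over the list alone used the p of the same fit. Means of the lists of other cell types and library measures were compared by exact permutation tests (two-sided) over every arrangement of 6 against 6 mice, whose smallest p is 0.00216, adjusted over lists and pairs of ages. Correlations of measures over libraries were computed within an age, with exact permutation p, and those between libraries of different ages have no p.

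For each pair of ages the rule for naming genes took the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 4 and at least 5 of 6 libraries of each age beyond the median of the other. For 20 weeks against the mean of the other ages it took 5 and 5, with at least 10 of the 12 other libraries beyond the median. Immunoglobulin and T cell receptor segments, genes named Gm or Rik, pseudogenes and mitochondrial transcripts were kept out of those ranks. The rule adds up to 4 called members of each list described, by smallest p, and each of the single genes that could be tested, and the text gives a part of the genes it names. Some of them are not reported here. Light chain segments, ribosomal RNA genes other than those the ranks name and the B cell surface genes were chosen after their values were seen.

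The alternatives were other scaling factors (RLE and upper quartile), DESeq2 1.42.0, limma-voom with quality weights, no filter or a stricter filter on low counts (10 CPM in 6 libraries), only the 2 ages compared, the replicate number as a block, immunoglobulin and other cell type genes left out, covariates (B and plasma cell lists, library total), and each of the 18 libraries left out in turn. Chosen after seeing the data were a correction by a loess curve per library for gene length or for GC content, fitted outside the ribosomal and oxidative phosphorylation lists, the log2 CPM of ribosomal RNA genes as a covariate, CPM summed over all genes of a list of another cell type in place of the mean log2 CPM, and a fit without replicate 3 of 20 weeks and replicate 5 of 26 weeks. The loess curves also shift the level of each library, so these corrections rescale libraries as well as remove a trend with length or GC content. Each count of called genes was compared with that of 100 splits of the libraries, the real one included, drawn with a fixed seed.

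The steps were tested on simulated data with known changes. Of genes changed 1.5, 2 and 4 times, edgeR recovered 4.48%, 10.4% and 43.9% between 20 and 14 weeks, 0%, 23.9% and 48.5% between 26 and 14 weeks, 2.99%, 17.9% and 50% between 26 and 20 weeks, and 5.97%, 20.9% and 48.5% for 20 weeks against the mean of the others. Unchanged genes called were 2, 2, 0 and 1, with 9720 or 9736 simulated genes tested. Each simulation changed 200 genes, fewer than the real tests called. The adjusted threshold depends on that number, so these shares need not hold for the real tests. Camera called 2 of 2 changed lists and 0 others in each of the comparisons of 20 and 26 with 14 weeks. Simulated genes were drawn independently, so this does not test camera on lists whose genes are correlated. In the real data the estimated correlation was, for example, 0.542 for the ribosomal list. With a length trend added between ages, unchanged genes called went from 752 to 2 with the length correction, and recovered genes from 76 to 47 of 200. Gene symbols without enough counts were left out of the tests, and reads themselves were not used here.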

Results

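Gene expression was measured in neutrophils sorted from the spleens of female NZBWF1/J mice, a hybrid strain that develops a lupus-like disease with age. The series compares 3 stages of that disease, taken as ages of 14, 20 and 26 weeks, with 6 mice at each age and 1 RNA sequencing library per mouse. The cells were live (DAPI negative) and positive for Ly6B, CD11b and Ly6G with intermediate Ly6C. Libraries held 5546624 to 17256379 gene counts, and 10104 of the 17941 gene symbols had enough counts to be tested. Levels below are means ± SD over 6 mice in CPM, counts scaled to the size of the library. Log2 fold changes are fitted values ± SE with edgeR's adjusted p, and gene lists were tested with camera.

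The libraries differed in composition with age. The 10 most abundant genes of a library took 22.7 ± 2.92% of its counts at 14 weeks, 13.4 ± 2.95% at 20 weeks and 29.7 ± 5.46% at 26 weeks. An exact permutation test (two-sided) gave adjusted p = 0.00648 for 20 against 14 and for 26 against 20 weeks, and 0.0562 for 26 against 14 weeks. Genes annotated as ribosomal RNA took 0.0233 ± 0.00237%, 0.0284 ± 0.0145% and 0.183 ± 0.145% at the 3 ages (adjusted exact p = 0.00648 for 26 weeks against either younger age, the smallest adjusted value reached). They include the mitochondrially encoded genes mt-Rnr1 and mt-Rnr2. The first 3 principal components held 25.7%, 13% and 11.2% of the variance. Replicate 3 of 20 weeks stood apart on the first of them, at 230, and had counts in 8119 genes. Its median correlation with the other libraries of its age was 0.756.

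**Figure D1:**
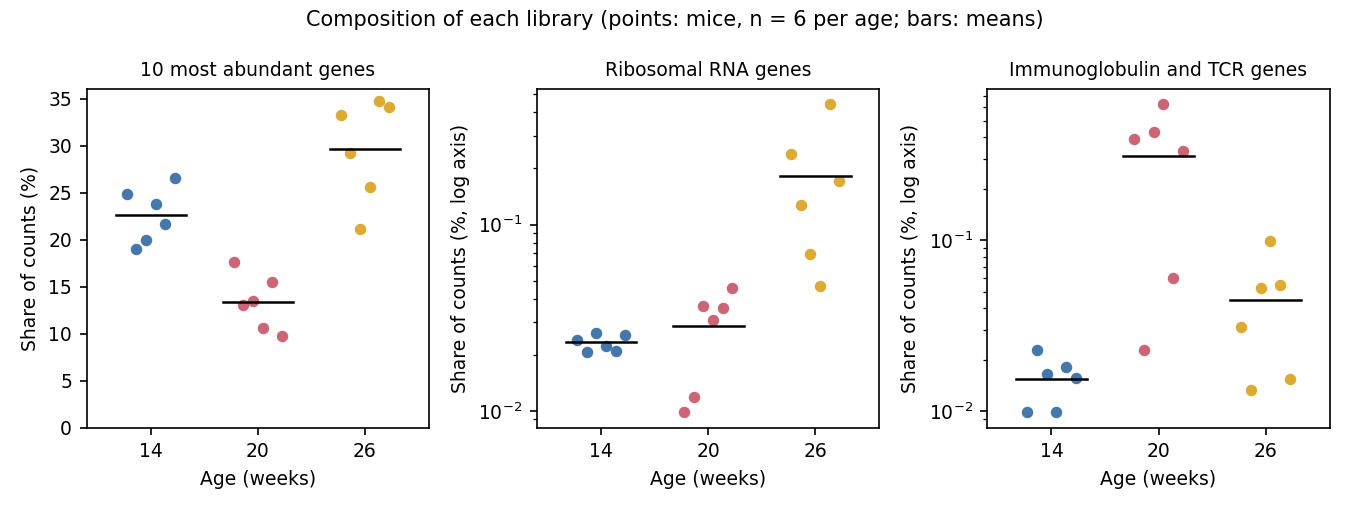
Composition of each library by age. Each point is 1 mouse (6 per age) and each bar the mean, for the share of counts in the 10 most abundant genes (linear axis, %), in genes annotated as ribosomal RNA (log axis, %) and in immunoglobulin and T cell receptor genes (log axis, %). The rRNA share was 0.183 ± 0.145% at 26 weeks against 0.0233 ± 0.00237% at 14 weeks (mean ± SD).

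Between 14 and 20 weeks, the list of secondary granule genes was called lower and those of cytokines, immediate early factors and mature neutrophils higher. These calls were lost with an estimated correlation (adjusted p = 0.109, 0.109, 0.0722 and 0.166 with an estimated correlation). The complement component C3 fell from 1020 ± 67.5 to 233 ± 92 CPM (log2 change -2.13 ± 0.23, adjusted p = 5.94e-05). Thbs1, which encodes thrombospondin 1, fell from 830 ± 131 to 162 ± 84.3 CPM (-2.36 ± 0.37, adjusted p = 0.000641). Clec4n, which encodes the lectin receptor Dectin-2, rose from 8.97 ± 5.56 to 146 ± 32.7 CPM (4.02 ± 0.44, adjusted p = 5.94e-05). The checkpoint ligand gene Cd274 (PD-L1) rose from 9.22 ± 4.15 to 88.6 ± 24.3 CPM (3.26 ± 0.51) and Csf1, the macrophage growth factor, from 46.7 ± 23 to 371 ± 160 CPM (2.99 ± 0.43). In all, 1030 genes were called, 498 higher and 532 lower at 20 weeks. In the GRCm38 build with GENCODE M21 gene models, C3 spans 57203970 to 57228136 on chromosome 17 and Thbs1 118111876 to 118127133 on chromosome 2. Clec4n spans 123229843 to 123247021 on chromosome 6, Cd274 29367455 to 29388095 on chromosome 19 and Csf1 107741048 to 107760469 on chromosome 3.

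Of 17 tested genes of the secondary granules, which neutrophil precursors fill before they leave the bone marrow, 13 fell, 0 rose and 4 were not called (15 fell when adjusted over the list alone). Camera called the list (adjusted p = 2.46e-11, adjusted p = 0.109 with an estimated correlation). Mmp8, the neutrophil collagenase gene, changed by -1.36 ± 0.20, Lcn2, which encodes lipocalin 2, by -1.53 ± 0.26, and Cybb, the catalytic subunit of the NADPH oxidase, by -1.28 ± 0.22. Ltf, which encodes lactoferrin, fell from 50600 ± 11000 to 18300 ± 10000 CPM. Ngp, the neutrophilic granule protein gene, fell by 0.87 ± 0.24, a call lost in 6 of the 18 fits that left out 1 library (adjusted p up to 0.0685). Of 7 primary granule genes 0 were called (0 when adjusted over the list alone, camera adjusted p = 0.442). The tertiary granule and secretory list, with 4 of 19 genes higher and 9 lower (6 and 10 when adjusted over the list alone), was not called either (camera adjusted p = 0.353). In the NADPH oxidase list, 3 of 14 genes fell and 0 rose (5 fell when adjusted over the list alone), among them Ncf1 (-1.19 ± 0.19). That list had camera adjusted p = 0.0116 (adjusted p = 0.091 with an estimated correlation). Ly6g (-1.37 ± 0.30), Itgam (-0.84 ± 0.19) and Ly6c2 (-1.66 ± 0.28) also fell, and their proteins belong to the sorting gate. Of 10 regulators and markers of immature neutrophils, 2 fell and 0 rose (2 when adjusted over the list alone). Camera gave that list adjusted p = 0.00354 (adjusted p = 0.109 with an estimated correlation).

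In the list of mature neutrophil genes, 9 of 23 rose and 0 fell (13 when adjusted over the list alone). It was called by camera (adjusted p = 5.13e-08, adjusted p = 0.166 with an estimated correlation). Il1b, the interleukin 1 beta gene, rose from 638 ± 333 to 2570 ± 836 CPM (2.01 ± 0.35), and Btg2 (0.76 ± 0.16) and Grina (0.77 ± 0.16) rose too. Of 14 cytokine and chemokine genes 5 rose and 0 fell (9 when adjusted over the list alone), with Ccl6 at 1.30 ± 0.32 and Cxcl2, a neutrophil chemoattractant, at 2.47 ± 0.64. In the NF-kB pathway list 6 of 26 genes rose and 0 fell (8 rose and 1 fell when adjusted over the list alone), including Nfkb2 (1.22 ± 0.30) and Icam1 (3.09 ± 0.59). The unfolded protein response list had 6 of 26 genes higher and 0 lower (9 when adjusted over the list alone), such as Hspa5 (0.91 ± 0.22) and Xbp1 (1.06 ± 0.15), which also belongs to the plasma cell list. Camera called the cytokine list (adjusted p = 4.18e-06, adjusted p = 0.109 with an estimated correlation) and the NF-kB list (adjusted p = 0.000104, adjusted p = 0.0899 with an estimated correlation). The unfolded protein list was called as well (adjusted p = 0.000105, adjusted p = 0.109 with an estimated correlation).

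Of 34 anti-inflammatory and suppressive genes 8 rose and 5 fell between 14 and 20 weeks (12 and 6 when adjusted over the list alone). The list was higher by camera (adjusted p = 0.00202, adjusted p = 0.222 with an estimated correlation). Socs3, a feedback inhibitor of cytokine signalling, rose by 2.27 ± 0.33, Tgfb1, the transforming growth factor beta 1 gene, by 1.16 ± 0.30 and the arginase gene Arg2 by 0.66 ± 0.20. The calls of Cxcl2 and Tgfb1 were lost without replicate 6 of 20 weeks (adjusted p = 0.0581 and 0.0565). That of Arg2 was lost in 7 of the 18 fits that left out 1 library (adjusted p up to 0.105).

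The immediate early and heat shock list, whose genes respond within minutes to stimulation and to tissue handling, had 16 of 22 genes higher at 20 weeks and 0 lower (19 when adjusted over the list alone). Its camera adjusted p was 1.64e-18 (adjusted p = 0.0722 with an estimated correlation). Nr4a1 rose from 11.2 ± 6.64 to 137 ± 50.3 CPM (3.61 ± 0.47), Junb by 2.25 ± 0.27 and Jund by 2.26 ± 0.31. The list shares 2 tested genes with the mature neutrophil list, 2 with the anti-inflammatory list, 1 with the unfolded protein list and 1, Nr4a1, with the monocyte and macrophage list.

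Interferon-inducible genes moved in both directions. Of 39 tested targets of type I interferon 1 rose and 3 fell (1 and 6 when adjusted over the list alone), and the list was not called (camera adjusted p = 0.384). Oasl2 rose by 0.85 ± 0.26, a call lost in 9 of the 18 fits that left out 1 library (adjusted p up to 0.101), and Samd9l fell by 1.77 ± 0.34. Isg15 (0.26 ± 0.27) and Irf7 (0.44 ± 0.25) were not called. Of 16 interferon gamma targets 5 rose and 0 fell (5 when adjusted over the list alone), Irgm2 by 1.17 ± 0.28 and Gbp9 by 1.32 ± 0.37 (lost in 5 of the 18 fits, adjusted p up to 0.0813). Camera called these targets higher (adjusted p = 0.00202, adjusted p = 0.267 with an estimated correlation). Tnfsf13b, the B cell survival factor BAFF, fell by 0.50 ± 0.16 (adjusted p = 0.0494), a call lost in 15 of the 18 fits that left out 1 library (adjusted p up to 0.113).

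Among glycolysis genes 6 of 22 fell and 1 rose (10 and 1 when adjusted over the list alone), with Gapdh at -0.93 ± 0.14 and Pgk1 at -1.05 ± 0.20. The list was lower by camera (adjusted p = 0.00202, adjusted p = 0.178 with an estimated correlation). Of the antigen presentation genes of MHC class II and its costimulators, 1 of 9 rose, Ctss by 2.10 ± 0.38 (2 when adjusted over the list alone). That list had camera adjusted p = 0.00432 (adjusted p = 0.181 with an estimated correlation).

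Markers of other cells moved over the same interval. The mean log2 CPM of the 3 tested plasma cell genes (Jchain, Igkc and Xbp1) rose from 1.95 ± 0.86 to 6.86 ± 1.65 (exact permutation test, two-sided, adjusted p = 0.0216), with Ighm at 98.4 ± 53.4 and 846 ± 604 CPM. That of 8 monocyte and macrophage genes rose from 6.28 ± 0.46 to 7.50 ± 0.26 (adjusted exact p = 0.0216), with Adgre1, the F4/80 gene, higher by 1.72 ± 0.34. Of these 8 genes 6 were called higher and 1, Ly6c2, lower (6 and 1 when adjusted over the list alone), and 1 of the 8, Nr4a1, is also in the immediate early list. The mean of 4 eosinophil genes rose from 0.97 ± 0.90 to 2.94 ± 0.68 (adjusted exact p = 0.026, and 0.0541 to 0.0649 without replicate 1, 2, 4, 5 or 6 of 20 weeks). Of these 4 genes 1 was called higher and 0 lower (3 higher and 1 lower when adjusted over the list alone). The mean of 3 basophil and mast cell genes fell from 5.65 ± 0.30 to 3.41 ± 1.28 (adjusted exact p = 0.0216), although the CPM summed over that list was 2345 ± 277 and 2329 ± 482 (adjusted exact p = 0.97). By edgeR 0 of these 3 genes were called (0 when adjusted over the list alone). Means of the B cell, T cell, dendritic cell, erythroid, platelet and stromal lists were not called between any ages (lowest adjusted exact p = 0.0649), and no gene of the NK cell list had enough counts. Summed over all genes of a list, a measure chosen after seeing the data, CPM gave other calls. The B cell sum was 122.6 ± 49.8 CPM at 14 and 1002 ± 650 CPM at 20 weeks (adjusted exact p = 0.00928), most of it Ighm, with 2 of 7 tested genes called higher (2 when adjusted over the list alone). Sums of the dendritic cell list were 12.6 ± 5.66 and 64.1 ± 22.6 CPM, of the T cell list 169.6 ± 16.9 and 107.8 ± 34.2 CPM and of the stromal list 57.8 ± 13.4 and 22 ± 14.1 CPM (adjusted exact p = 0.00928, 0.00928 and 0.00999). In these lists 1 of 4 tested genes was called higher, 0 of 7 were called and 1 of 3 was called lower (2, 1 and 1 when adjusted over the list alone). With the mean of the B cell and plasma cell lists as a covariate, 22 genes were called between 20 and 14 weeks, and camera's calls of the immature neutrophil, NADPH oxidase, class II and glycolysis lists were lost (adjusted p = 0.223, 0.208, 0.422 and 0.223). The plasma cell mean itself rose over that interval, so the covariate overlaps with age and these losses do not tell other cells from age. With immunoglobulin and other cell type genes left out instead, 1029 genes were called. DESeq2 called 1725 genes, and corrections for gene length or GC content moved the share of calls that were higher from 48.3% to 74.2% and 74.4%, and ended the call of the NADPH oxidase list (adjusted p = 0.165 and 0.145) and, for length, of the glycolysis list (0.0878). These corrections also rescale each library, so such moves need not come from length or GC content.

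**Figure D2:**
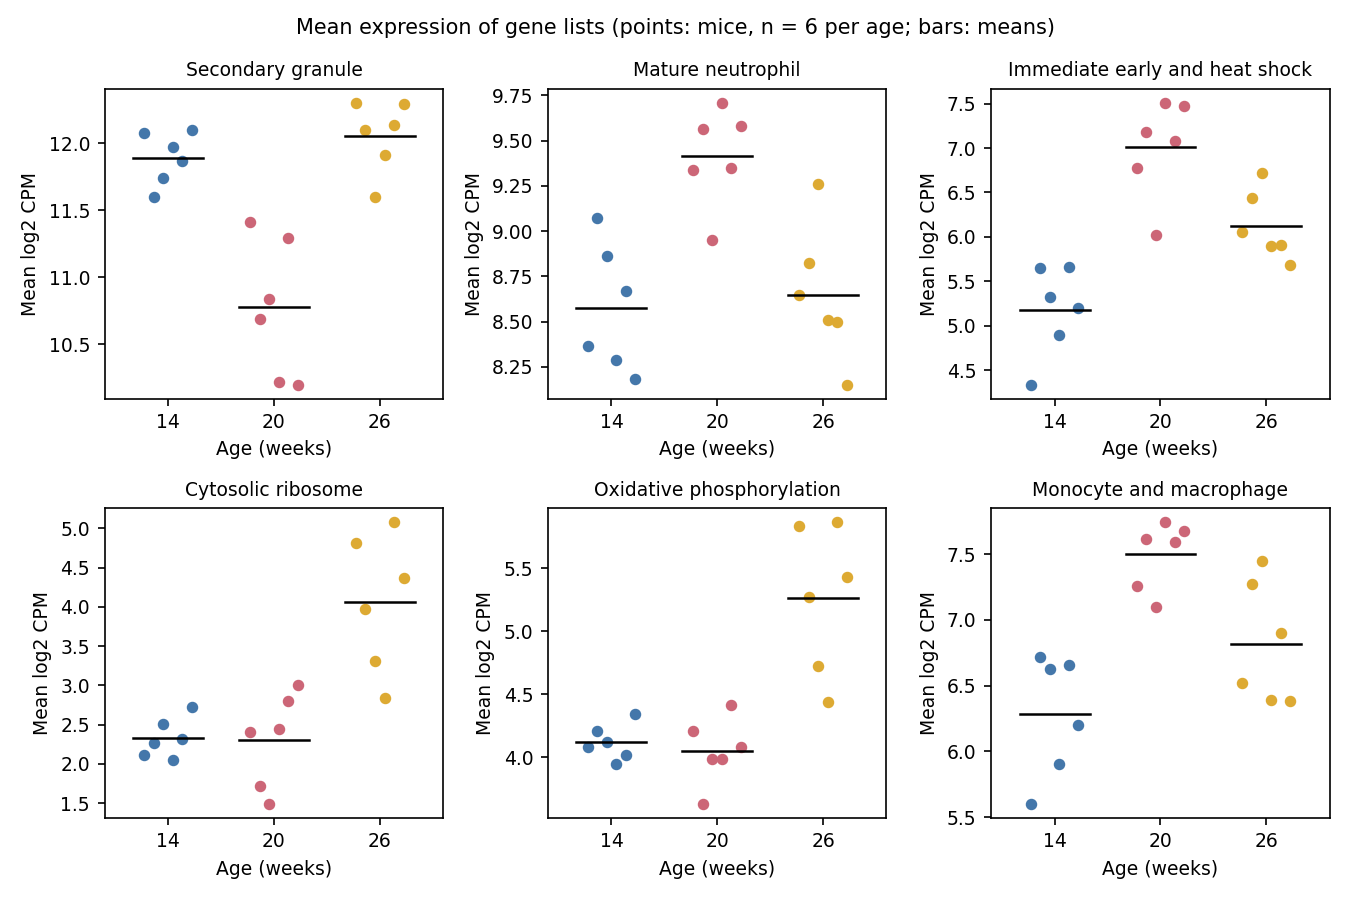
Mean expression of 6 fixed gene lists in each library (log2 CPM, averaged over the tested genes of the list). Each point is 1 mouse (6 per age) and each bar the mean. The 17 secondary granule genes were lowest at 20 weeks on average, with 13 called lower than at 14 weeks, while 16 of 22 immediate early genes were called higher.

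Between 14 and 26 weeks, 46 of 67 genes of the cytosolic ribosome and 30 of 47 of oxidative phosphorylation rose and both lists were called higher, while the lists of Fc and complement receptors and of Toll-like receptors and nucleic acid sensors were called lower. The sensing list had adjusted p = 0.408 with an estimated correlation and the other 3 lists adjusted p = 0.213 with an estimated correlation, so these calls were lost. S100a8, a subunit of the alarmin calprotectin, rose from 4720 ± 488 to 24500 ± 18000 CPM (2.38 ± 0.40, adjusted p = 0.00155), and S100a9 by 1.45 ± 0.34. The interleukin 17 receptor gene Il17ra (-1.50 ± 0.22), the endosomal receptor gene Tlr13 (-1.57 ± 0.28) and the glucose transporter gene Slc2a3 (-1.23 ± 0.18) fell. Tagln2 rose by 2.63 ± 0.35 and the ecto-nucleotidase gene Nt5e (CD73) fell by 1.88 ± 0.44. The chemokine receptor gene Cxcr4 rose by 0.77 ± 0.19. Cxcr2, another chemokine receptor gene, fell by 0.61 ± 0.19, a call lost in 12 of the 18 fits that left out 1 library (adjusted p up to 0.12). The test called 1111 genes, 551 higher and 560 lower at 26 weeks. S100a8 spans 90668978 to 90670035 on chromosome 3, Tlr13 106143204 to 106160493 on chromosome X and Slc2a3 122727809 to 122801640 on chromosome 6 (GRCm38, GENCODE M21).

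Of 67 tested genes of the cytosolic ribosome 46 rose and 0 fell (63 when adjusted over the list alone), with a median log2 change of 1.92, including Rps27 (2.64 ± 0.42) and Rps3 (1.63 ± 0.26). Of 47 oxidative phosphorylation genes 30 rose and 0 fell (39 when adjusted over the list alone), with a median of 1.33, including Cox6c, from 10.9 ± 2.37 to 56.5 ± 33.1 CPM. Camera called both lists, with adjusted p = 5.35e-28 and 4.17e-18, and each had adjusted p = 0.213 with an estimated correlation. Ribosomal protein genes have many processed pseudogenes, and how reads shared with them were counted is not given in the sources used here. Of 5 tested genes annotated as ribosomal RNA 3 rose and 0 fell over the same interval, Rn18s-rs5 from 34.5 ± 12.6 to 1060 ± 1140 CPM (4.94 ± 0.72). Yam1 rose by 3.85 ± 0.62 and Lars2, a mitochondrial leucyl-tRNA synthetase gene, by 3.74 ± 0.59. Mitochondrially encoded transcripts rose too, 7 of 10 with 0 lower (median 1.87). The mitochondrial ribosomal RNA genes mt-Rnr1 and mt-Rnr2 are in both groups, so these 2 counts overlap. Within the 26 week libraries, ribosomal RNA and the mean of the ribosomal protein list ranked the 6 mice identically (Spearman rho = 1, exact permutation p = 0.00278, adjusted over 6 relations 0.00834). Pearson r was 0.989 (exact p = 0.00139) and 0.999 without the 2 farthest mice. At 14 and 20 weeks rho was 0.486 (exact p = 0.356) and 0.371 (exact p = 0.497).

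Granule genes were divided at 26 weeks. In the secondary granule list 5 of 17 rose and 1 fell (6 and 4 when adjusted over the list alone), and the list was not called (camera adjusted p = 0.515). Camp, the cathelicidin gene (1.86 ± 0.38), and Lcn2 (1.09 ± 0.26) were higher and Mmp8 (-0.99 ± 0.20) lower. Ly6g, whose protein belongs to the sorting gate, was higher too (1.18 ± 0.30). Of 7 primary granule genes 1 rose, Fcnb, which encodes ficolin B, by 2.74 ± 0.54 (2 when adjusted over the list alone, camera adjusted p = 0.0583). In the tertiary granule and secretory list 5 of 19 rose and 3 fell (5 and 4 when adjusted over the list alone, camera adjusted p = 0.681). There Wfdc21 was higher (2.28 ± 0.42) and the gelatinase gene Mmp9 lower (-0.90 ± 0.15). Cell cycle genes had 6 of 33 higher and 0 lower (7 when adjusted over the list alone), among them Stmn1, at 0.885 ± 0.999 CPM at 14 and 5.76 ± 1.18 CPM at 26 weeks, and Cenpa (1.06 ± 0.29). Stmn1 was not called without replicate 4 of 14 weeks (adjusted p = 0.0501), nor Cenpa without replicate 5 of 26 weeks (0.0628). Camera called the cell cycle list (adjusted p = 6.71e-12, adjusted p = 0.0899 with an estimated correlation).

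Of 18 Fc and complement receptor genes 6 fell and 1 rose (7 and 1 when adjusted over the list alone), with Inpp5d, the inhibitory phosphatase SHIP-1, at -1.21 ± 0.20 and Fcer1g at 1.00 ± 0.23. Of 28 Toll-like receptor and nucleic acid sensing genes 7 fell and 1 rose (7 and 1 when adjusted over the list alone), with Tlr5 at -1.40 ± 0.32. Camera called the Fc receptor list (adjusted p = 0.00311, adjusted p = 0.213 with an estimated correlation) and the sensing list (adjusted p = 0.0173, adjusted p = 0.408 with an estimated correlation). Of 39 type I interferon targets 5 fell and 1 rose (6 and 2 when adjusted over the list alone), including the RNA sensor gene Ddx58 (-1.10 ± 0.24) and Oas3 (-1.20 ± 0.29). The interferon list had camera adjusted p = 0.0277 (adjusted p = 0.502 with an estimated correlation), a call lost without replicate 5 of 14 weeks (adjusted p = 0.0922) or replicate 4 of 26 weeks (0.179). Glycolysis genes had 7 of 22 lower and 1 higher (10 and 3 when adjusted over the list alone), with camera adjusted p = 0.0173 (adjusted p = 0.408 with an estimated correlation).

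Class I presentation genes had 5 of 18 higher and 0 lower (7 when adjusted over the list alone), with B2m at 1.22 ± 0.22. Antioxidant genes had 6 of 24 higher and 1 lower (6 and 1 when adjusted over the list alone), with Txn1, the thioredoxin gene, at 1.43 ± 0.27. Both lists had camera adjusted p = 0.0232 (adjusted p = 0.408 with an estimated correlation), and that of class I was 0.0809 without replicate 6 of 14 weeks. In the cytokine list 1 of 14 genes was higher, Il1b by 1.36 ± 0.34 (3 when adjusted over the list alone), and in the immediate early list 3 of 22 were higher and 1 lower (10 and 1 when adjusted over the list alone). These 2 lists were called with camera adjusted p = 0.00989 and 0.00207, and each had adjusted p = 0.408 with an estimated correlation.

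Plasma cell genes averaged 4.98 ± 2.21 log2 CPM at 26 weeks (adjusted exact p = 0.078 against 14 weeks), with 3 of 3 tested genes called higher by edgeR (3 when adjusted over the list alone), although Igkc and Xbp1 were not called in 8 and 7 of the 18 fits that left out 1 library. Summed over the list, plasma cell genes stood at 371.5 ± 229 CPM at 26 and 154.5 ± 20.3 CPM at 14 weeks (adjusted exact p = 0.00999). By that measure the erythroid sum was higher (adjusted exact p = 0.0478), with 271.1 CPM in replicate 6 of 26 weeks and at most 35.7 CPM in the other 5, and the platelet and stromal sums lower (0.0469 and 0.00928), with 0 of 2, 1 of 4 and 0 of 3 tested genes called (0, 1 and 0 when adjusted over the list alone). Basophil and mast cell genes fell to a mean of 4.28 ± 1.09 log2 CPM (adjusted exact p = 0.026 against 14 weeks, and 0.0505 to 0.0649 without replicate 1, 2, 4, 5 or 6 of 14 weeks), with Hdc at -0.80 ± 0.19. With ribosomal RNA as a covariate edgeR called 0 genes between 26 and 14 weeks (425 at an unadjusted p under 0.05; without the covariate DESeq2 called 1804 and limma-voom 2633), Lars2, Cxcr4, Fcer1g and Padi4 took the opposite sign (-0.03, -0.09, -0.18 and 0.22), and 3 gene lists were called in place of 11 (cell cycle, immediate early and tertiary granule, the last at a median of -0.17). The count was 457 after a correction for gene length (without the class I and antioxidant lists, adjusted p = 0.166 and 0.087), 657 with the B and plasma cell covariate (without the interferon and glycolysis lists, adjusted p = 0.238 and 0.128), 1710 with only the 2 ages in the fit, and 652, 733 and 726 without replicates 1, 2 and 6 of 26 weeks, while GC correction ended the class I call (0.0524) and upper-quartile factors moved the share of calls that were higher from 49.6% to 62%.

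Between 20 and 26 weeks, secondary granule, ribosomal and respiratory lists were called higher, and the lists of mature neutrophil genes, immediate early genes, Fc and complement receptors and Toll-like receptors and nucleic acid sensors lower. All 7 calls were lost with an estimated correlation (adjusted p = 0.204 to 0.209 with an estimated correlation). Lcn2 rose from 4400 ± 1530 to 27000 ± 10500 CPM (2.62 ± 0.27, adjusted p = 3.47e-05), S100a8 by 3.58 ± 0.42 and Ngp from 30100 ± 11900 to 94900 ± 21800 CPM (1.66 ± 0.25). Thbd, the thrombomodulin gene, fell from 96.1 ± 50.2 to 10.8 ± 7.54 CPM (-3.13 ± 0.54), and Fgl2 (-2.07 ± 0.43) and the interleukin 1 receptor accessory protein gene Il1rap (-2.04 ± 0.30) also fell. Cxcr4 rose by 0.66 ± 0.19, a call lost without replicate 2 of 20 weeks or replicate 1 or 5 of 26 weeks (adjusted p = 0.0525 to 0.0578). The test called 1617 genes, 811 higher and 806 lower at 26 weeks. The 20 week libraries enter both this comparison and the one with 14 weeks, so opposite changes in the 2 are not independent. Lcn2 spans 32384633 to 32388252 on chromosome 2, Ngp 110419747 to 110423012 on chromosome 9 and Thbd 148404466 to 148408188 on chromosome 2 (GRCm38, GENCODE M21).

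Of the genes in the secondary granule list 12 of 17 rose and 0 fell (13 when adjusted over the list alone), among them the lysozyme gene Lyz2 (1.38 ± 0.20) and Ly6g (2.56 ± 0.31), whose protein belongs to the sorting gate. Immature neutrophil genes had 4 of 10 higher and 0 lower (4 when adjusted over the list alone), including Cebpe, a transcription factor of granule gene expression (1.18 ± 0.29), and Cd63 (1.06 ± 0.18). Camera called both, with adjusted p = 3.27e-10 and 0.0058, and each had adjusted p = 0.204 with an estimated correlation. Mature neutrophil genes had 10 of 23 lower and 0 higher (13 when adjusted over the list alone), including Csf3r, the G-CSF receptor gene (-1.70 ± 0.30). Cell cycle genes had 10 of 33 higher and 1 lower (14 and 2 when adjusted over the list alone), with Hmgb2 at 0.77 ± 0.13 and Kif23 at -1.32 ± 0.26. The mature list (camera adjusted p = 1.33e-08) and the cell cycle list (1.27e-05) each had adjusted p = 0.204 with an estimated correlation. In the cell cycle list 3 genes had 0 counts in all 6 libraries of 20 weeks. With those set to the fold against 3 counts over the age the list median stayed at 2.13, though 3 of 33 folds can hardly move a median.

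The ribosomal list had 43 of 67 genes higher and 0 lower (59 when adjusted over the list alone), with Rpl7 at 1.65 ± 0.26 and Rps29 at 3.22 ± 0.51. The oxidative phosphorylation list had 30 of 47 higher and 1 lower (35 and 1 when adjusted over the list alone), with Uqcrc2 at 1.05 ± 0.18. Camera gave them adjusted p = 1.86e-16 and 2.25e-10, and both had adjusted p = 0.209 with an estimated correlation. Of the 5 ribosomal RNA genes 4 rose and 0 fell, Rn18s-rs5 by 5.87 ± 0.76, and all 10 tested mitochondrial transcripts rose (median 2.74). Both counts include mt-Rnr1 and mt-Rnr2.

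Of 22 immediate early and heat shock genes 12 fell and 0 rose (12 when adjusted over the list alone), with Hspa8 at -1.19 ± 0.15. The Fc and complement receptor list had 7 of 18 lower and 1 higher (9 and 1 when adjusted over the list alone), with the C5a receptor gene C5ar1 at -0.93 ± 0.15. The anti-inflammatory list had 14 of 34 lower and 4 higher (18 and 4 when adjusted over the list alone). There Socs3 stood at -1.82 ± 0.33, Il1rn, the interleukin 1 receptor antagonist gene, at -0.68 ± 0.17 and the inhibitory receptor gene Clec12a at 1.05 ± 0.18. Camera called these 3 lists, with adjusted p = 1.62e-08, 2.39e-05 and 0.000165, and each had adjusted p = 0.204 with an estimated correlation. Toll-like and nucleic acid sensing genes had 7 of 28 lower and 1 higher (9 and 1 when adjusted over the list alone), with Tlr4 at -1.79 ± 0.28 and the inflammasome gene Nlrp3 at -1.87 ± 0.34. The NF-kB list had 5 of 26 lower and 0 higher (5 when adjusted over the list alone), with Rela at -0.79 ± 0.19. Both had adjusted p = 0.209 with an estimated correlation, against camera adjusted p = 0.00314 and 0.0134.

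Class II and costimulation genes had 3 of 9 lower and 0 higher at 26 than at 20 weeks (3 when adjusted over the list alone), with Cd80 at -1.23 ± 0.38, a call lost in 7 of the 18 fits that left out 1 library (adjusted p up to 0.0812). They had camera adjusted p = 0.0121 (adjusted p = 0.22 with an estimated correlation). Unfolded protein response genes had 5 of 26 lower and 0 higher (6 lower and 2 higher when adjusted over the list alone). Their camera adjusted p was 0.0346 (adjusted p = 0.346 with an estimated correlation), and 0.0524 to 0.0798 without replicate 4 of 20 weeks or replicate 1 or 4 of 26 weeks. The glycolysis list was not called (8 of 22 higher, 5 lower, 8 and 6 when adjusted over the list alone, camera adjusted p = 0.85), although Gapdh rose by 1.25 ± 0.14. Neither was the type I interferon list (4 of 39 higher, 3 lower, 4 and 3 when adjusted over the list alone, camera adjusted p = 0.267), whose median of -0.27 and mean of 0.03 differ in sign.

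Monocyte and macrophage genes averaged 6.82 ± 0.46 log2 CPM at 26 weeks against 7.50 ± 0.26 at 20 weeks (adjusted exact p = 0.0649). Of the 8, 5 fell while Ly6c2 rose by 2.35 ± 0.28 (5 and 1 when adjusted over the list alone), and camera called the list lower (adjusted p = 0.0107, adjusted p = 0.209 with an estimated correlation). Summed CPM of the monocyte, B cell, plasma cell, dendritic cell, eosinophil and basophil lists was lower at 26 than at 20 weeks (adjusted exact p from 0.00928 to 0.0365) and that of the T cell list higher (0.0382). Mean log2 CPM went the other way for the dendritic cell list (1.77 at 26 and 1.74 at 20 weeks) and the basophil list (4.28 and 3.41), without a call (adjusted exact p = 0.942 and 0.276). With ribosomal RNA as a covariate 7 genes were called between 26 and 20 weeks, the direction camera gave the ribosomal list was reversed, as was that of Cxcr4 (-0.14), and the calls of the oxidative phosphorylation, immature neutrophil, NF-kB, Toll-like and unfolded protein lists were lost (adjusted p = 0.79, 0.0532, 0.11, 0.162 and 0.11). DESeq2 called 2554 genes and the fit with the B and plasma cell covariate 1073, without the class II and unfolded protein lists (adjusted p = 0.131 each), and corrections for gene length or GC content, which also rescale each library, moved the share of calls that were higher from 50.2% to 26.8% and 29.1%.

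**Figure D3:**
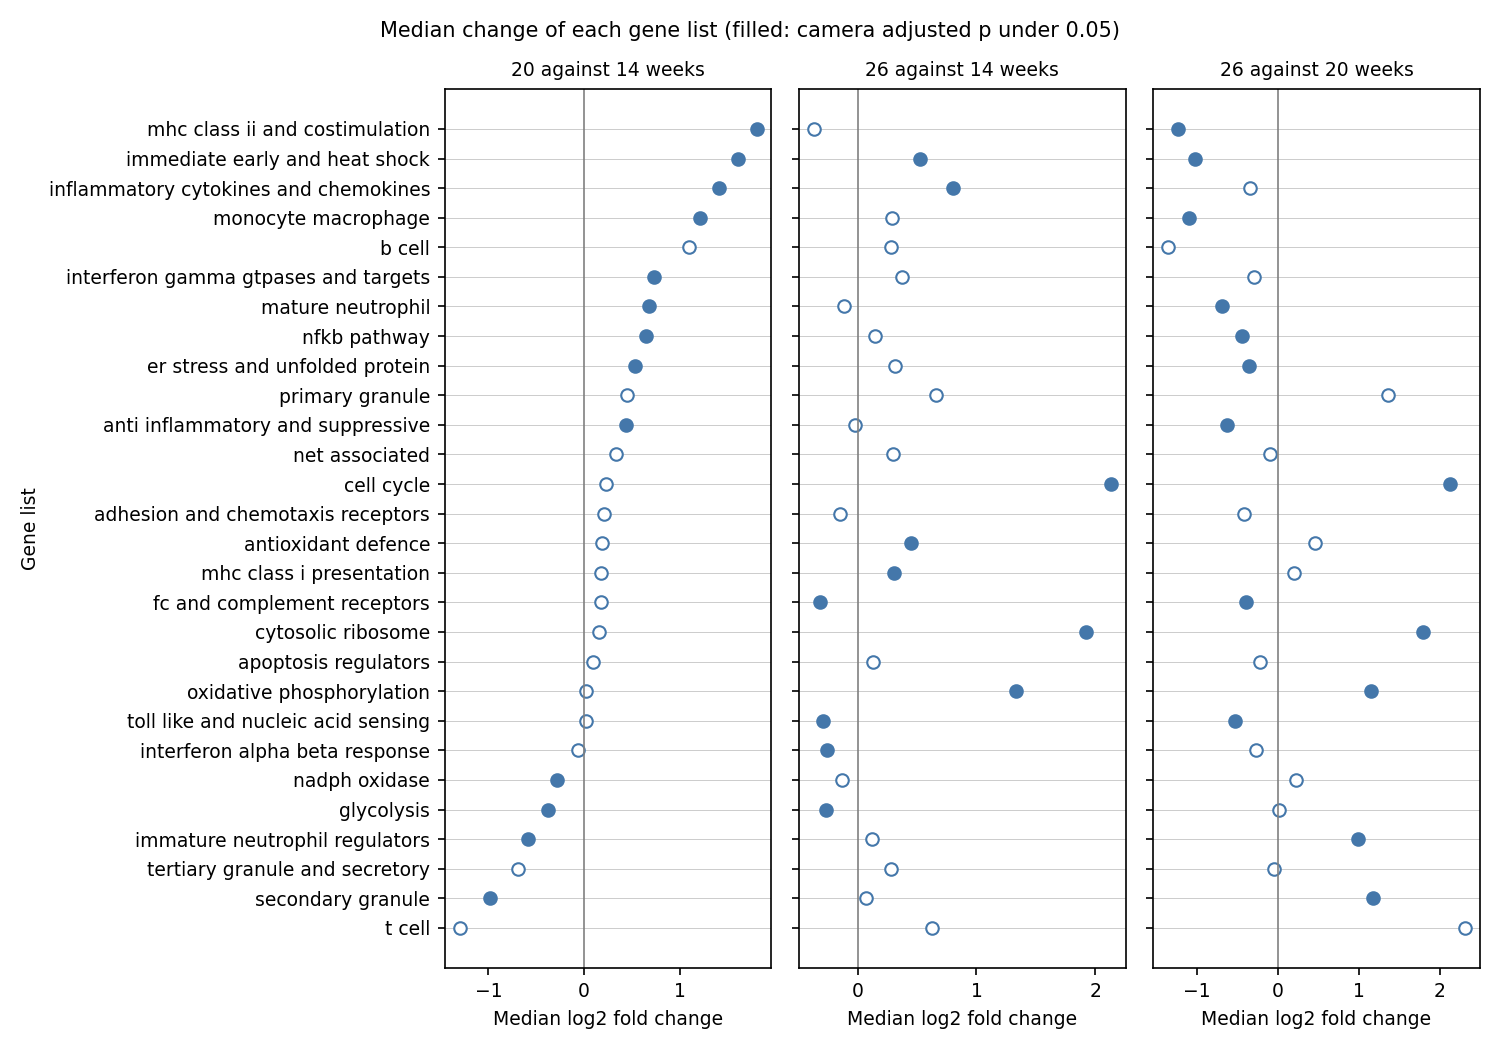
Median log2 fold change of each tested gene list in the 3 pairwise comparisons. Filled points mark lists called by camera with a preset correlation of 0.01 (adjusted p under 0.05), and open points the rest. With an estimated correlation 0 of 28 lists were called in each comparison, and with fry 13, 10 and 18.

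Set against the mean of the younger and older age, 20 weeks differed in 1512 genes, 823 higher and 689 lower. Thbd (2.90 ± 0.42, adjusted p = 0.000224), Pmaip1, which encodes the pro-apoptotic protein Noxa (2.73 ± 0.56), Cd274 (2.58 ± 0.39), Nr4a1 (2.57 ± 0.35) and Csf1 (2.49 ± 0.33) were higher at 20 weeks. Lcn2 (-2.07 ± 0.24), S100a8 (-2.39 ± 0.37) and Wfdc21 (-2.43 ± 0.39) were lower. Of the secondary granule genes 16 of 17 were lower and 0 higher (16 when adjusted over the list alone), and of the mature neutrophil genes 12 of 23 were higher and 0 lower (16 when adjusted over the list alone). Camera called the granule list (adjusted p = 1.44e-12, adjusted p = 0.144 with an estimated correlation) and the mature list (adjusted p = 3.98e-10, adjusted p = 0.147 with an estimated correlation). Anti-inflammatory genes had 16 of 34 higher and 4 lower (17 and 5 when adjusted over the list alone), with Il1rn at 0.57 ± 0.15 and Arg2 at 0.67 ± 0.17. Monocyte genes had 6 of 8 higher and 1 lower (6 and 1 when adjusted over the list alone). Camera called these lists with adjusted p = 0.000206 (adjusted p = 0.168 with an estimated correlation) and 0.000451 (adjusted p = 0.147 with an estimated correlation). The 3 plasma cell genes, too few for camera, were all called higher (3 when adjusted over the list alone), Igkc not in 7 of the 18 fits that left out 1 library. The covariates, which themselves differed between ages, left 199 calls (B and plasma cells) and 838 (ribosomal RNA), and DESeq2 called 2303. Corrections for gene length or GC content, which also rescale each library, each moved the share of calls that were higher from 54.4% to 77.4%.

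**Figure D4:**
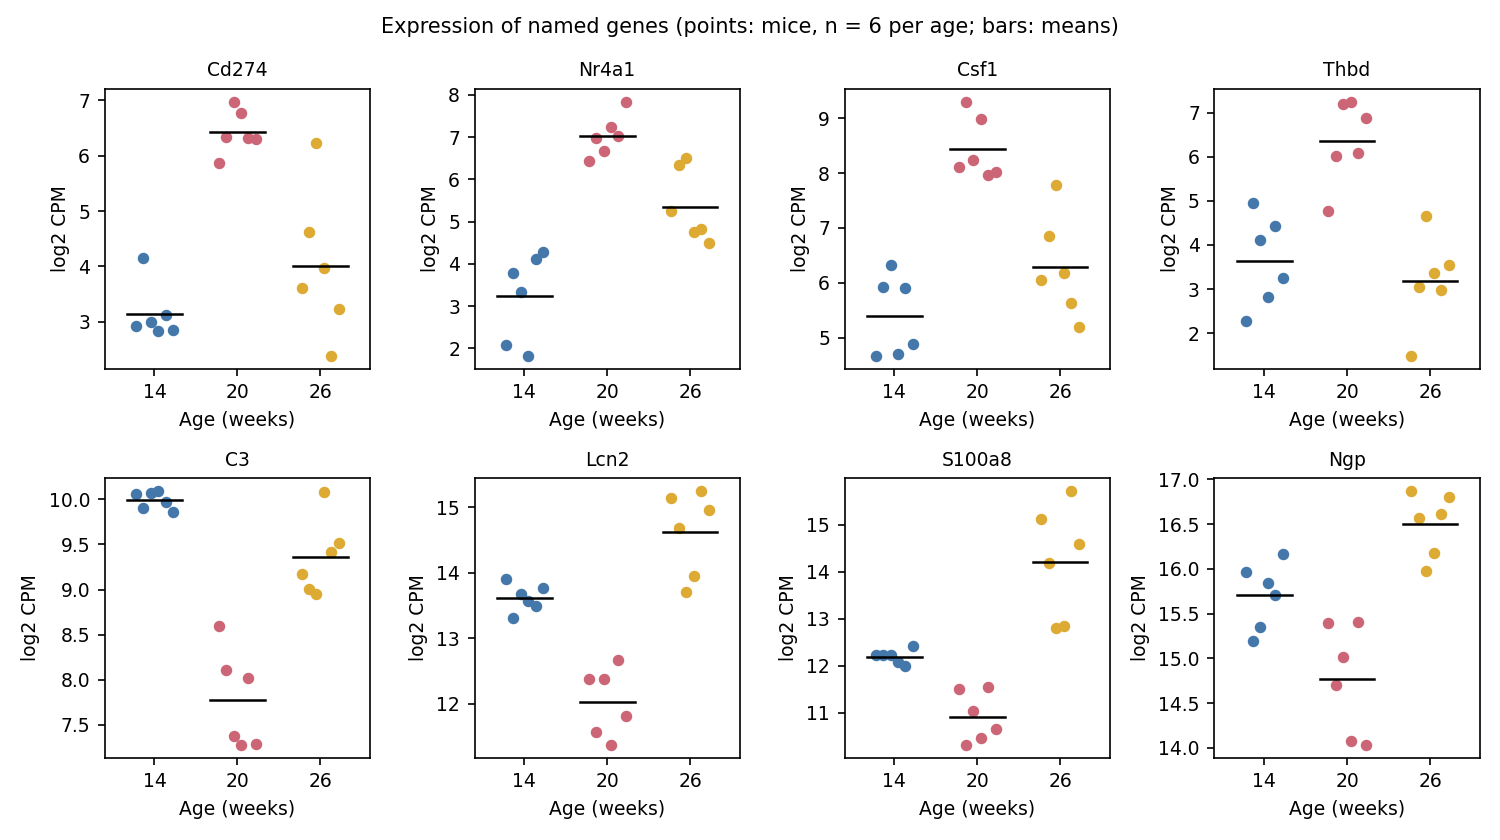
Expression of 8 named genes in each library (log2 CPM). Each point is 1 mouse (6 per age) and each bar the mean. Cd274, Nr4a1, Csf1 and Thbd were highest and Lcn2, S100a8 and Ngp lowest on average at 20 weeks, and C3 went from 1020 ± 67.5 CPM at 14 weeks to 233 ± 92 CPM at 20 weeks (mean ± SD).

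Across the 3 ages 2321 genes were called with age at any stage, and 22 of the 29 tested genes that had been fixed singly were among them. Fixed genes not called in that test of any change with age included Cxcr2 (edgeR adjusted p = 0.0515), Irf7 (0.13), Isg15 (0.329), Tlr7 (0.351), Tnf (0.382) and Fcgr4 (0.544). Cxcr2 was nonetheless called in the comparison of 26 with 14 weeks. Il6, Il10, Arg1, Mpo, Elane and Tnfsf13 had too few counts to be tested, with a highest count of 21 in any library for Il6. Padi4, which citrullinates histones in extracellular trap formation, stood at -0.80 ± 0.25 in both 20 and 26 weeks against 14 weeks (adjusted p = 0.0496 and 0.0455). Its call was lost in 16 and 13 of the 18 fits that left out 1 library. The count for any stage was 824 with ribosomal RNA as a covariate, 1398 with the B and plasma cell covariate and 4005 with limma-voom.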

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

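The tests of dilution by other cells, of plasma cell RNA and of B cells were chosen only after the result was seen, as were the gene length and ribosomal RNA settings.

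A library lay far from the other 5 of its age in 30 of 447 groups of values examined: 0 of 18 for library measures, 12 of 105 for the mean log2 CPM of a gene list and 18 of 324 for the log2 CPM of a gene. Chance gives about 1 in 20 groups. Replicate 3 of 20 weeks stood apart 9 times and replicate 1 of 14 weeks 5 times. The value and the nearest other library of the same age follow for each.

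Replicate 3 of 20 weeks was lowest in the anti-inflammatory list (6.59, nearest 7.09), the Fc and complement receptors (8.62, nearest 8.78), the cytokines and chemokines (3.58, nearest 5.44), the interferon gamma targets (2.41, nearest 4.32), the Toll-like and nucleic acid sensors (4.02, nearest 5.14), the eosinophil list (1.59, nearest 2.94) and Tlr7 (0.93, nearest 4.11). It was highest in Mmp9 (13.19, nearest 12.79) and Tlr5 (5.68, nearest 4.64). Replicate 1 of 14 weeks was lowest in the apoptosis regulators (3.86, nearest 4.36), the unfolded protein response list (3.78, nearest 4.49), Hspa5 (7.33, nearest 7.80), Icam1 (-2.43, nearest 1.39) and Pmaip1 (-2.43, nearest 3.14).

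Replicate 1 of 20 weeks was lowest in C5ar1 (11.23, nearest 11.74), Fgl2 (9.82, nearest 11.32) and Il1rap (7.06, nearest 8.22), and replicate 2 of 20 weeks in Txn1 (7.06, nearest 7.47). The T cell list was highest in replicate 5 of 20 weeks (2.50, nearest 0.78). Replicate 2 of 14 weeks was lowest in Ly6g (9.83, nearest 10.28) and Fpr2 (7.87, nearest 8.39) and highest in Cd274 (4.15, nearest 3.13). The class II and costimulation list was highest in replicate 6 of 14 weeks (3.89, nearest 2.16), where Oas3 was lowest (7.20, nearest 8.04). Pgk1 was highest in replicate 3 of 14 weeks (6.85, nearest 6.53).

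Replicate 1 of 26 weeks was lowest in the basophil and mast cell list (2.21, nearest 4.27) and Oas3 (5.84, nearest 6.77). Replicate 5 of 26 weeks was lowest in the dendritic cell list (0.35, nearest 1.76). In replicate 4 of 26 weeks B2m was lowest (10.32, nearest 11.47) and Itgam highest (10.83, nearest 9.98).

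Ribosomal protein and oxidative phosphorylation genes were higher at 26 than at 14 weeks, with list medians of 1.92 and 1.33 on the log2 scale. Gene length bias is argued against as the whole cause for the ribosomal list, whose median was 1.66 after the length correction (0.819 of the uncorrected value, jackknife SE 0.0793), and stays open for oxidative phosphorylation (0.969, a share of 0.708 with SE 0.0811). Carry-over of ribosomal RNA or a difference in RNA quality stays open for both, since with ribosomal RNA as a covariate the medians were 0.259 and 0.281 (shares of 0.193, SE 0.213, and 0.201, SE 0.303). Ribosomal RNA itself rose at 26 weeks, from 0.0233 ± 0.00237% to 0.183 ± 0.145% of counts, so that covariate and age overlap in part. The covariate takes in the mitochondrial genes mt-Rnr1 and mt-Rnr2, so it does not measure cytosolic ribosomal RNA alone. Within the 26 week libraries both lists followed ribosomal RNA (Spearman rho = 1 for each, exact permutation p = 0.00278, adjusted over 6 relations 0.00834). At 14 and 20 weeks rho was 0.486 and 0.371 for the ribosomal list and 0.257 and 0.143 for oxidative phosphorylation (exact p from 0.356 to 0.803). These relations do not tell RNA quality from a change in the cells. A change in the cells with age stays open and was not tested apart from these.

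Secondary granule genes were lower and mature neutrophil genes higher at 20 than at 14 weeks, with list medians of -0.982 and 0.676. Other cells diluting the neutrophils stay open: the mature list's median of 0.676 (SE over its members 0.365) is part of the pattern itself, and monocytes, whose genes rose from 6.28 ± 0.46 to 7.50 ± 0.26 log2 CPM, could feed that list. Monocytes or their RNA would have had to pass a sort for Ly6G positive cells with intermediate Ly6C. Of the 8 tested monocyte genes 6 were called higher and 1 lower, and 1 of the 8, Nr4a1, is shared with the immediate early list. The gene called lower was Ly6c2, whose protein belongs to the sorting gate. With the immediate early and heat shock list as a covariate, the granule median was -0.37 (a share of 0.42, SE 0.404), which leaves transcripts induced during handling open. The mature list, with the shared genes left out, went from 0.586 to -0.0951 (a share of -0.228, SE 0.558), which meets by a narrow margin the bound set for handling as its cause, so that handling may account for that part. A difference in cell maturity with age stays open and was not tested apart from these, since the covariate list itself rose at 20 weeks.

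Immunoglobulin, T cell receptor and Jchain transcripts together took a larger share of counts at 20 than at 14 weeks (mean log2 percent -2.39 and -6.08, exact permutation test, adjusted p = 0.0111). Of 22 tested immunoglobulin and T cell receptor genes 2 rose and 0 fell, with a median log2 change of -0.814. The share in replicate 2 of 20 weeks, 0.0228%, was no higher than the 0.0229% of replicate 2 of 14 weeks. A candidate explanation is RNA of a few plasma cells per library, present although the sort took cells positive for Ly6G and CD11b. Of 5 libraries of 20 weeks with at least 200 counts in light chain variable segments, 4 had at least 80% of them in 1 segment. In these 5 libraries 5 different segments led (Iglv1, Iglv3, Iglv2, Igkv12-89 and Igkv4-59), and Jchain lay between 28.9 and 1010 CPM. At 26 weeks 2 of 4 such libraries did, and at 14 weeks 0 libraries had that many counts, while 3 of the 16 genes of the plasma cell list in the table could be tested and 1 of them, Xbp1, also belongs to the unfolded protein list. A wider admixture of B cells stays open, because over the 6 libraries of 20 weeks the immunoglobulin share and the summed B cell surface transcripts had a Spearman rho of -0.0857 (exact permutation p = 0.919, jackknife SE 0.638) and a Pearson r of 0.131 (exact p = 0.811, and -0.112 without the 2 farthest libraries). More plasma cells in the spleen with age stay open too, and were not tested.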

How the results depend on the processing

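The gene length, GC content, ribosomal RNA and summed CPM settings and the fit without replicate 3 of 20 weeks and replicate 5 of 26 weeks were chosen only after the result was seen.

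Counts of called genes stayed within 1.5 times their value under RLE and upper-quartile factors, both filters on low counts, the library total covariate, the GC correction, the fit without immunoglobulin and other cell type genes and that without the 2 outlying libraries, the last calling 1225, 1060, 1398 and 1503 genes in the 4 comparisons and 2261 at any stage (917, 893, 1194, 1220 and 1903 of them the same genes). With the replicate block the counts were 962, 946, 1573, 1390 and 2081 (866, 876, 1437, 1281 and 1963 the same genes), and the cell cycle list lost its call for 20 weeks against the mean of the others (adjusted p = 0.0562). The replicate numbers do not pair the mice: libraries with the same number had r from -0.0434 to 0.0984 after the age means were removed, and 4 of 18 ranked their own number first.

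Other settings moved counts by over 1.5 times, and the cause was not tested. DESeq2 called 1725, 1804, 2554 and 2303 genes in 20 against 14, 26 against 14, 26 against 20 and 20 against the mean of the others. Calls by limma-voom were 2633 for 26 against 14 weeks and 4005 at any stage. With only the 2 ages in the fit 26 against 14 weeks gave 1710. The B and plasma cell covariate left 22, 657, 1073 and 199 in those comparisons and 1398 at any stage (22, 619, 1001, 189 and 1324 the same genes). Plasma cell genes themselves rose at 20 weeks, so that covariate and age overlap in part. The length correction gave 457 for 26 against 14 weeks (418 the same). With ribosomal RNA as a covariate edgeR called 0 genes for 26 against 14 weeks (425 at an unadjusted p under 0.05), 7 for 26 against 20 weeks (1224 unadjusted), 838 for 20 weeks against the mean of the others and 824 at any stage. Camera with an estimated correlation called 0 of 28 lists in each of the 4 comparisons, against 13, 11, 14 and 16 with the preset one and 13, 10, 18 and 18 by fry, and 3 lists were called in 26 against 14 weeks with ribosomal RNA as a covariate.

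Without 1 library the counts ran from 702 to 1263 (20 against 14 weeks), 652 to 1544 (26 against 14 weeks, with 652, 733 and 726 without replicates 1, 2 and 6 of 26 weeks), 1141 to 1911 (26 against 20 weeks), 1069 to 1740 (20 weeks against the mean of the others) and 1780 to 2682 (any stage), and the lists called from 13 to 15, 10 to 13, 13 to 17 and 15 to 17.

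Directions were reversed under the ribosomal RNA covariate and, for 4 other cell type results, with summed CPM, and the cause was not tested. With the covariate the list medians were -0.1675 (tertiary granule) and 0.1292 (antioxidant, by camera's direction) for 26 against 14 weeks, 0.1395 (ribosome, by camera's direction) for 26 against 20 weeks, and -0.09541 (oxidative phosphorylation, by camera's direction) and 0.02101 (ribosome) for 20 weeks against the mean of the others. For genes they were -0.09454 (Cxcr4), -0.1801 (Fcer1g), -0.01096 (Fpr2), -0.03469 (Lars2) and 0.2218 (Padi4) for 26 against 14 weeks, and -0.1966 (B2m), -0.1423 (Cxcr4) and 0.132 (Hdc) for 26 against 20 weeks. With summed CPM in place of mean log2 CPM the differences that turned were -41.21 (dendritic cell) and -1005 (basophil and mast cell) for 26 against 20 weeks and -30.22 (platelet) and -27.66 (stromal) for 26 against 14 weeks, each called in the direction opposite to that of the mean, which was not called. With these 4, 15 results gained a call, while 1 lost its call and 14 stayed on the same side of the threshold. Calls of named genes were lost 131 times with the ribosomal RNA covariate, 119 times with the B and plasma cell covariate, 43 with the length correction, 26 with the GC correction, 224 over all fits without 1 library and 15 times or fewer under each other setting. Calls of lists by camera with the preset correlation were lost 15, 11, 5, 2 and 14 times and at most 1 time. Those counts of lists leave out fry and the estimated correlation, under which every camera call was lost.

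The RLE and upper-quartile factors moved the median of all genes by at most 0.0982 on the log2 scale. The length correction moved it by 0.171, 0.0424, -0.19 and 0.2 in the 4 comparisons and the GC correction by 0.194, -0.0206, -0.209 and 0.202. Each fitted curve carries a level of its own, so a change of scaling was not told apart from the removal of a length or GC trend. The alternative for normalized values was not run, since the table holds counts, and the fit of only 2 ages gives no value for 20 weeks against the mean of the others or for any stage. Of the 100 splits of the libraries 1, the real one, called as many genes in each comparison, which makes a random split an unlikely source. The calls were 1030 against 250 in the highest other split, 1111 against 885, 1617 against 748, 1512 against 93 and, at any stage, 2321 against 0. For each pair of ages that highest other split kept 10 of 12 libraries in their real place. Splits cannot test a difference in batch or RNA quality that runs with age. Depth may limit genes with few counts, which was not tested, and changes of 2 times were recovered in 10.4% to 23.9% of simulated genes.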

Other observations

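The length and GC corrections named in this part were chosen only after the result was seen.

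Receptors for adhesion and chemotaxis moved in both directions with age. Between 14 and 20 weeks 8 of 28 rose and 9 fell (10 and 9 when adjusted over the list alone), and the list was not called by camera (adjusted p = 0.438). Ceacam1, which encodes a carcinoembryonic antigen family receptor, fell from 683 ± 71.2 to 263 ± 93.6 CPM (-1.38 ± 0.21). The integrin beta 2 gene Itgb2 changed by -0.67 ± 0.12, a call lost after the length and GC corrections, which also rescale each library (adjusted p = 0.143 and 0.221). The chemerin-binding receptor gene Ccrl2 rose from 50.4 ± 34.8 to 288 ± 113 CPM (2.51 ± 0.46). Between 20 and 26 weeks 5 rose and 7 fell (5 and 9 when adjusted over the list alone, camera adjusted p = 0.0528). There Fpr2, a formyl peptide receptor gene, rose by 1.86 ± 0.25 and Ltb4r1, the leukotriene B4 receptor gene, by 1.24 ± 0.19, while Itgal, the LFA-1 alpha chain gene, fell by 1.03 ± 0.17. Between 14 and 26 weeks 5 rose and 6 fell (6 and 9 when adjusted over the list alone, camera adjusted p = 0.165).

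Regulators of apoptosis had 5 of 25 genes higher and 1 lower at 20 than at 14 weeks (5 and 2 when adjusted over the list alone, camera adjusted p = 0.111). The pro-apoptotic genes Pmaip1 (3.54 ± 0.75) and Bcl2l11, which encodes Bim (2.25 ± 0.52), rose, as did the TNF receptor gene Tnfrsf1a (0.65 ± 0.16). At 26 weeks 2 genes of the list were higher and 3 lower than at 20 weeks (4 and 8 when adjusted over the list alone, camera adjusted p = 0.281), among the latter Tnfrsf1a (-0.80 ± 0.16). The ferritin genes Ftl1 (1.02 ± 0.22) and Fth1 (0.94 ± 0.24) of the antioxidant list rose between 14 and 20 weeks, when 3 of its 24 genes rose and 4 fell (4 and 5 when adjusted over the list alone, camera adjusted p = 0.631). Of 10 genes associated with extracellular traps 1 rose, Hmgb1 by 0.77 ± 0.19, and 1 fell, Padi4 (1 and 1 when adjusted over the list alone, camera adjusted p = 0.384). With the B and plasma cell covariate, all of the gene calls between 20 and 14 weeks given here were lost (adjusted p from 0.113 to 0.668). Plasma cell genes rose over the same interval, so this loss does not tell other cells from age.

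NF-kB genes had 7 of 26 higher and 0 lower at 20 weeks than at the mean of 14 and 26 weeks (9 when adjusted over the list alone). Camera called the list (adjusted p = 0.000451, adjusted p = 0.144 with an estimated correlation). Cell cycle genes had 6 of 33 lower and 2 higher in that comparison (7 and 2 when adjusted over the list alone). The cell cycle list was called (adjusted p = 0.0467, adjusted p = 0.408 with an estimated correlation), and was not in 8 of the 18 fits that left out 1 library, nor with the replicate number as a block.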
